A study of Homo sapiens with 6 samples.

How the data were processed

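Gene expression was measured by RNA sequencing in U118, an established human malignant glioma cell line, at day 2 after siRNA transfection. The 6 libraries were 1 of wild-type cells (WT), 1 of cells given a control siRNA (siNC) and 4 of cells given siRNA against RIPK2 (siRIPK2_1 to siRIPK2_4). The WT cells are taken here as untransfected. Per the labels' protocols, mRNA was enriched from total RNA through its poly(A) tail, fragmented and copied from random primers. The authors deposited 1 table of raw counts per Ensembl gene ID, with no normalisation. Per the submitters' processing notes, FastQC, Trimmomatic, HISAT2 and bedtools were used with the genome build GRCh38. Tool versions, the annotation release and the strand setting of the counting are not given in the sources used here. Reads from overlapping or antisense genes therefore cannot be told apart, and 5320 of the 20263 listed IDs have exons that overlap another listed gene.

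Gene symbols were matched for 20148 IDs, and 20224 IDs were found in GENCODE release 29, which supplied GRCh38 coordinates, gene lengths, GC content and 3' UTRs. All 6 columns matched 1 sample each by name. Total counts ranged from 33540619 to 45309423 per library. A level of 3 counts, used as the detection floor, corresponds to between 0.0662 and 0.0894 CPM (counts scaled by library size), and such floors cover counting error only. Duplicate libraries were checked with a chi-square statistic over genes with more than 20 counts in a pair. It ranged from 77.1 to 223.6 per degree of freedom, so every pair differed far beyond sampling noise and all libraries were kept.

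Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr with a minimum count of 10, quasi-likelihood F test) with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. One fit with 3 groups over all 6 libraries gave siRIPK2 against siNC, siRIPK2 against WT and siNC against WT. Its 3 residual degrees of freedom come from the siRIPK2 libraries, so each lone control library is assumed to vary as they do. A fit with 2 groups set the 4 siRIPK2 libraries against both controls together, with 4 residual degrees of freedom. The labels do not say whether siRIPK2_1 to siRIPK2_4 are different siRNAs, separate cultures or repeat transfections. The p-values therefore measure only the spread between these libraries, which may hold technical differences or differences between siRNAs. RIPK2, the targeted gene, was read with its unadjusted p as a single gene set in advance and with its adjusted p. Its exact permutation test used all 15 splits of the 6 libraries into 2 and 4.

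In total 29 gene lists were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison. The correlation was also estimated from the data, and fry, which asks whether a list's genes move on balance in 1 direction, was run as well. Each list's median was set against 10000 random lists matched on mean expression. Levels per library are CPM with TMM factors, and list levels per library are on the log2(CPM + 1) scale. The lists, groups, tests, most of the alternatives and the rule for named genes were fixed before the data were examined.

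The rule named RIPK2 first. It then took up to 12 genes per direction with an adjusted p under the threshold against siNC, a mean of at least 5 CPM and all 4 siRIPK2 libraries on the same side of both controls. Places left over were filled by the lowest unadjusted p under the same conditions and given as values without a call. RIPK2 itself took 1 of the 12 lower places. From each list up to 4 members with the lowest unadjusted p against siNC and at least 1 CPM could be named. For siNC against WT the rule gave the 3 lowest p in each direction as values, since no gene passed. Genes that mark a single library were chosen after their values were seen.

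The tests were checked on simulated counts drawn from the real means, library sizes and dispersions for 14306 genes, with 50 genes changed at each fold size. Against siNC, edgeR recovered 0% of 2-fold, 38% of 4-fold, 80% of 8-fold and 86% of 16-fold changes. Against WT it recovered 2%, 38%, 92% and 90% of the same sizes, and against both controls 8%, 62%, 82% and 94%. For siNC against WT it recovered 0%, 10%, 52% and 86%. Among the unchanged genes it called 7, 8, 8 and 5 in these comparisons. All fold sizes were present together in each run, which eases the Benjamini-Hochberg threshold for each of them. The shares may therefore overstate what the real data could yield. RIPK2 itself, at a mean of 11.6% of its WT level, did not pass in edgeR. A simulated list shifted by a log2 of 0.5 reached an adjusted p of 0.0103 in camera with the preset correlation, with 0 of 99 unshifted lists called. With an estimated correlation the shifted list had an adjusted p of 0.967, so that setting missed the shift in this 1 simulation. The simulated genes were drawn independently, whereas the estimated correlation of the real lists reached 0.762 (G2/M and mitosis, fit with 3 groups). The simulation therefore cannot show how often the preset correlation calls unshifted lists whose members move together.

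Alternatives were DESeq2 size factors or the upper quartile in place of TMM, no filter (at least 1 count), and a stricter filter (at least 50 counts in every siRIPK2 or every control library). Further ones were the DESeq2 1.42.0 Wald test, limma-voom, robust dispersions, and leaving out each siRIPK2 library or a control library. Length and GC offsets per library, and testing only genes without the heptamers described next, were added after seeing the data. For the heptamer search, each library's deviation from the median of the other 5 was taken for 10560 genes with at least 5 CPM and a 3' UTR of at least 50 nucleotides. It was limited to a log2 of 2, adjusted for UTR length and GC content, and regressed on the presence of each heptamer found in at least 50 genes. Tested on simulated data, this found a heptamer planted at a log2 of -0.3 in 10 of 10 runs. Weaker effects were not simulated, and those of the picked heptamers on even-numbered chromosomes included -0.089 in siRIPK2_2 and -0.182 in siNC. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Sequencing reads were not analysed here.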

Results

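The series profiled U118 cells, a human malignant glioma line, at day 2 after transfection with siRNA against RIPK2, a kinase that relays signals from the NOD1 and NOD2 receptors to NF-kB and MAP kinases. Its stated subject is what loss of RIPK2 does to these cells. There were 4 siRIPK2 libraries, 1 siNC library and 1 WT library. The total count was 35782060 in WT, 33540619 in siNC, and 38798207, 39439406, 45309423 and 37243009 in siRIPK2_1 to siRIPK2_4. Between 13390 and 13823 genes had at least 10 counts in a library. Mitochondrially encoded transcripts took between 4.1% of counts in siRIPK2_2 (95% exact binomial interval 4.091% to 4.103%, counting error only) and 4.71% in siRIPK2_1 (4.706% to 4.72%), with 4.64% in siNC (4.635% to 4.649%). The 2 controls have no replicates, so their values carry no SD.

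RIPK2 (ENSG00000104312, chromosome 8, 89757747 to 89791063 on the plus strand, GRCh38) was lower in all 4 siRIPK2 libraries than in both controls. Its level was 56.8 CPM in WT and 43.4 CPM in siNC. It was 3.86, 11.9, 6.27 and 4.32 CPM in siRIPK2_1 to siRIPK2_4, a mean of 6.58 ± 3.67 CPM (SD, n = 4). The knockdown mean was 15.1% of the siNC level and 11.6% of the WT level. The highest residual level, in siRIPK2_2, was 27.3% of siNC. As a single gene set in advance, RIPK2 fell by 2.72 on the log2 scale against siNC (SE 0.526, unadjusted p of 0.000946 in edgeR). It fell by 3.11 against WT (unadjusted p of 0.000384) and by 2.93 against both controls (unadjusted p of 8.17e-05, the lowest of all 13901 genes tested). Adjusted over all genes, these edgeR values were 0.972, 1 and 0.739, and RIPK2 did not pass. Over the alternatives against both controls, its adjusted p ranged from 1.74e-06 in DESeq2 to 1 in edgeR without siNC. In siNC, RIPK2 was lower than in WT by less than the spread allows (log2 fold change -0.39, unadjusted p of 0.624). The exact permutation test over the 15 splits of the libraries gave a 2-sided p = 0.0667, the smallest that this design allows.

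**Figure D1:**
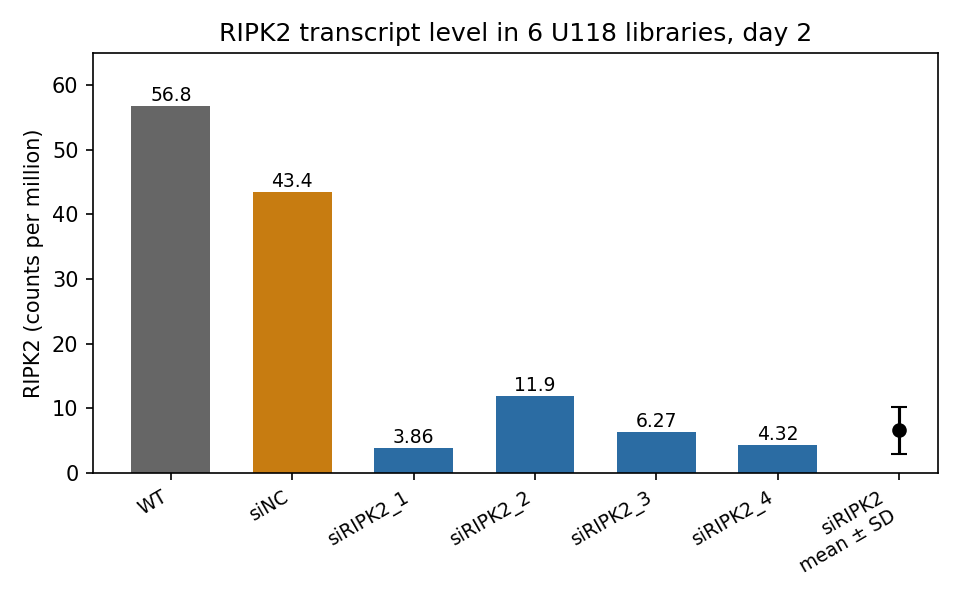
RIPK2 level in CPM (y axis) in each of the 6 libraries (bars), with the mean and SD of the 4 siRIPK2 libraries as a black point with error bar. The siRIPK2 libraries lie between 3.86 and 11.9 CPM, below siNC at 43.4 and WT at 56.8 CPM.

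Against the siRNA control, the knockdown libraries held less transcript of glycolytic, NF-kB-dependent and cholesterol-synthesis genes. The hypoxia and glycolysis list fell by a median of 0.63 on the log2 scale, with 29 of 30 measured members lower. The NF-kB target list fell by a median of 0.72, with 25 of 29 members lower. Cholesterol biosynthesis fell by a median of 0.42 (20 of 24 lower), mesenchymal glioma markers by 0.34 (18 of 24 lower) and mitochondrially encoded transcripts by 0.23 (13 of 13 lower). All 5 list medians were below siNC in 4 of 4 siRIPK2 libraries, but siRIPK2_1 lay only 0.024 below in mitochondrial transcripts (the others 0.21 to 0.41) and 0.053 below in cholesterol biosynthesis (the others 0.36 to 0.55), in log2(CPM + 1). The siNC library itself lay above WT in NF-kB targets and in hypoxia and glycolysis, by medians of 1.27 and 0.54. It lay 0.22 above WT in mitochondrial transcripts and 0.20 in mesenchymal markers, against 0.02 in cholesterol biosynthesis. Against the preset correlation of 0.01, the estimate was 0.384 for hypoxia and glycolysis, 0.126 for NF-kB targets and 0.697 for mitochondrial transcripts. It was 0.0991 for cholesterol biosynthesis and 0.0234 for mesenchymal markers. With the preset value camera judges the spread between genes, which does not measure replication of the lone siNC library. In fry no list passed. The adjusted p in camera was 5.21e-13 for hypoxia and glycolysis, 1.2e-10 for NF-kB targets, 0.00312 for cholesterol biosynthesis, 0.0221 for mesenchymal markers and 0.0155 for mitochondrial transcripts. With an estimated correlation no list passed (adjusted p = 0.665 for the first 4 named and 0.886 for mitochondrial transcripts). The mitochondrial list also missed the threshold without siRIPK2_2 (adjusted p = 0.0593).

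Within these lists, single members are given as values, since none passed edgeR's adjusted threshold over all genes. Among glycolytic enzymes, GAPDH stood at 15240 CPM in siNC against 9746 ± 791 CPM (SD, n = 4) in the knockdown libraries and 10120 CPM in WT. ENO1 was at 9072 CPM in siNC and 6095 CPM in WT against 5714 ± 425 CPM, and PGK1, which overlaps another listed gene, at 1959 and 1029 CPM against 900.3 ± 191 CPM. Of the NF-kB targets, the growth factor gene CSF2 was at 19.7 CPM in siNC, 5.17 ± 2.34 CPM in siRIPK2 and 0.999 CPM in WT. The chemokine gene CXCL3 was at 29.6 CPM in siNC, 11.1 ± 2.2 CPM in siRIPK2 and 10.2 CPM in WT. TRAF1 and BIRC3, which act in TNF receptor signalling, were at 56.9 and 45.3 CPM in siNC and at 12.4 and 13.04 CPM in WT, against 21.1 ± 7.32 and 20.5 ± 4.88 CPM in siRIPK2. Among sterol enzymes, DHCR7 was at 6.83 CPM in siNC and 4.19 CPM in WT against 3.29 ± 0.538 CPM in siRIPK2. Of the mesenchymal markers, S100A10 was at 629 CPM in siNC, 234 CPM in WT and 254 ± 110 CPM in siRIPK2. In the same list 18 members were lower than in siNC and 6 higher. One of the higher ones, STAT3, was at 114 CPM in siNC, 121 CPM in WT and 186 ± 39.8 CPM in siRIPK2. Adjusted over the list alone, 0 members of these 5 lists passed in edgeR.

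The NOD-RIPK2 signalling list, the pathway of the target itself, had a median log2 fold change of 0.01 against siNC, with 12 members higher and 12 lower (adjusted p = 0.685 in camera). TNFAIP3, a target and inhibitor of NF-kB signalling, was at 137 CPM in siNC, 56.6 CPM in WT and 70.3 ± 15.2 CPM in siRIPK2. The other RIP kinase and inflammasome list had a median of -0.23 (adjusted p = 0.112), and its member RIPK1 was at 56.2 CPM in siNC, 41.6 CPM in WT and 41.9 ± 8.64 CPM in siRIPK2. MAPK and AP-1 response genes had a median of 0.03 (adjusted p = 0.636). Its member IER2, an immediate early gene, was at 49.1 CPM in siNC and 5.36 CPM in WT against 9.3 ± 3.46 CPM in siRIPK2, and passed in edgeR when adjusted over the list alone. Interferon-stimulated genes had a median of 0.06 (adjusted p = 0.685), with SAMD9 at 11.4 CPM in siNC, 25.6 CPM in WT and 30.9 ± 11 CPM in siRIPK2.

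With all 4 siRIPK2 libraries, lists tied to growth and survival did not pass against siNC. The median log2 fold change was 0.14 for G2/M and mitosis, -0.05 for DNA replication, -0.09 for p53 targets, -0.09 for apoptosis regulators and -0.05 for DNA repair. Their adjusted p in camera was 0.402, 0.38, 0.449, 0.86 and 0.456 in that order. Replication-dependent histones had a median of 0.52 (adjusted p = 0.449). Without siRIPK2_1, DNA replication passed as lower (adjusted p = 0.00736, and 0.842 with an estimated correlation) and histones as higher (0.0483 and 0.819). Without siRIPK2_2, G2/M and mitosis passed as higher (0.00108 and 0.818). Lists tied to invasion also did not pass: -0.04 for extracellular matrix (adjusted p = 0.39), -0.12 for migration and invasion (0.402), 0.04 for TGF-beta response (0.528) and 0.07 for YAP and TEAD targets (0.875). In the matrix list, POSTN, which encodes periostin, was at 14.6 CPM in siNC, 76.8 CPM in WT and 61.8 ± 11.6 CPM in siRIPK2, and passed in edgeR when adjusted over the list alone. COL1A1, a fibrillar collagen, was at 3436 CPM in siNC, 1800 CPM in WT and 1764 ± 445 CPM in siRIPK2. In the migration and invasion list, 3 members were higher and 1 lower than in siNC at an unadjusted p under 0.05 in edgeR. The lower one, the protease gene PLAU, which overlaps another listed gene, was at 587 CPM in siNC, 257 CPM in WT and 262 ± 117 CPM in siRIPK2. Of the higher ones, ZEB1 was at 10.2 CPM in siNC, 18.7 CPM in WT and 34.6 ± 14.5 CPM in siRIPK2. CTTN was at 133, 299 and 281 ± 48.3 CPM in the same order, and MMP16 at 28.7, 48.4 and 62.6 ± 20.3 CPM.

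The remaining lists had medians of -0.01 for the integrated stress response (adjusted p = 0.406), -0.09 for autophagy and lysosome (0.456) and -0.15 for nuclear-encoded oxidative phosphorylation (0.222). Cytosolic ribosomal proteins had -0.07 (0.402) and the small RNA pathway -0.16 (0.24), with AGO1, an Argonaute gene, at 58.2 CPM in siNC, 23.7 CPM in WT and 25.8 ± 4.44 CPM in siRIPK2. Markers of astrocytes and proneural glioma had a median of 0.10 (0.801), neurons and oligodendrocytes 0.25 (0.619), macrophages and microglia 0.15 (0.449), epithelium 0.23 (0.449) and endothelium -0.53 (0.258). Of the 15 macrophage and microglia markers 5 were measured, and 1 of them, LAPTM5, with a mean of 0.941 CPM and named after its values were seen, passed in edgeR when adjusted over the list alone. Of the 10 endothelial markers 7 were measured. Without siRIPK2_2 the integrated stress response passed as lower (adjusted p = 0.033, and 0.818 with an estimated correlation). Without siRIPK2_3, oxidative phosphorylation (0.0445 and 0.839) and ribosomal proteins (0.00731 and 0.839) did so. The median and the test, or the mean, had opposite signs for the NOD-RIPK2, MAPK, apoptosis, TGF-beta, YAP, DNA repair, astrocyte and macrophage lists, none of which passed.

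No single gene passed edgeR's adjusted threshold against siNC among 14306 tested, so the genes named by the fixed rule are values without a call. The 12 higher ones had log2 fold changes from 1.12 to 2.10 against siNC, but only from 0.11 to 0.70 against WT, where 0 of the 12 had an unadjusted p under 0.05. RANBP2, a nuclear pore protein, was at 40.3 CPM in siNC, 115 CPM in WT and 139 ± 16.3 CPM (SD, n = 4) in siRIPK2. STAG2 and NIPBL, a cohesin subunit and the cohesin loader, were at 33.8 and 19.4 CPM in siNC and at 86.2 and 49.1 CPM in WT, against 99.03 ± 8.71 and 56.3 ± 6.69 CPM in siRIPK2. The chromatin remodelling subunit SMARCD1 was at 44.3 CPM in siNC, 73.9 CPM in WT and 120 ± 18.5 CPM in siRIPK2. The others were MESD, ZNF91, EIF5B, RAB40C, PCNX3, DHX37, PPARG and EPN1. Besides RIPK2, 11 lower genes were named, with log2 fold changes from -1.92 to -0.91 against siNC, and 5 of them also had an unadjusted p under 0.05 against WT. A level below WT in all 4 siRIPK2 libraries was a condition of the rule, so the count against WT is not independent support. GOLM2, a Golgi membrane protein gene, was at 83.7 CPM in siNC, 95.2 CPM in WT and 34.4 ± 4.4 CPM in siRIPK2. The amino acid transporter gene SLC36A1 was at 53.05 CPM in siNC, 29.9 CPM in WT and 14.04 ± 5.55 CPM. The tubulin gene TUBA1B was at 4777 CPM in siNC, 4111 CPM in WT and 2435 ± 454 CPM, VASN at 214 and 219 CPM against 112 ± 20 CPM, and TBCEL at 34.3 and 31.2 CPM against 16.9 ± 2.82 CPM. The others were PCDHGA2, TMEM132A, COL6A1, TP53INP1, TNFAIP8L1 and GDPD5. Of the 23 genes, 8 overlap other listed genes, among them STAG2 and, with 21 others, PCDHGA2, and are uncertain for that reason.

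In edgeR, 0 genes passed against siNC and 682 had an unadjusted p under 0.05 (509 higher and 173 lower), where chance alone gives about 715. With the length and GC offsets, added after seeing the data, 398 were higher and 183 lower, and the log2 fold change of STAG2 went from 1.55 to 1.27. The DESeq2 Wald test called 74 genes, 69 of them higher, and limma-voom called 0. RIPK2 was among the lower calls (adjusted p = 0.00731 in DESeq2), and RANBP2 and STAG2 among the higher ones. POSTN and GANAB, also called, were at 14.6 and 279 CPM in siNC and at 76.8 and 872 CPM in WT. In siRIPK2 they were at 61.8 ± 11.6 and 803 ± 29 CPM, below WT. For genes of this kind the call reflects a low level in the lone siNC library, and it does not show a rise above WT. The biological coefficient of variation was 33.7%, and at this spread edgeR recovered 0% of simulated 2-fold and 38% of simulated 4-fold changes in this comparison.

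Against untransfected cells, cholesterol biosynthesis was again lower, whereas NF-kB targets were higher in the knockdown libraries. Cholesterol biosynthesis fell by a median of 0.31 on the log2 scale, with 21 of 24 members lower. NF-kB targets rose by a median of 0.35 with 22 of 29 members higher, the reverse of their direction against siNC. In log2(CPM + 1), their median lay 0.51 above WT in siRIPK2_2 but only 0.09, 0.13 and 0.16 above it in siRIPK2_1, siRIPK2_3 and siRIPK2_4. Targets of YAP and TEAD rose by a median of 0.28 (17 of 22 higher), MAPK and AP-1 response genes by 0.22 (20 of 28), cytosolic ribosomal proteins by 0.18 (33 of 37) and the small RNA pathway by 0.13 (11 of 15). Over the alternative settings the mean log2 fold change ranged from 0.0142 to 0.235 for ribosomal proteins. It ranged from 0.105 to 0.26 for the small RNA pathway and from 0.12 to 0.247 for the MAPK list. The YAP target F3, which encodes tissue factor, was at 19.1 CPM in WT and 50.3 ± 19.2 CPM (SD, n = 4) in siRIPK2, and the phosphatase gene DUSP5 at 71.3 CPM against 154.7 ± 60.9 CPM. The median was above WT in 4 of 4 siRIPK2 libraries for NF-kB, YAP, MAPK and small RNA lists, but in only 2 of 4 for ribosomal proteins. With the length and GC correction the median was 0.23 for the MAPK list and 0.15 for the small RNA list, no smaller than before.

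The adjusted p in camera against WT was 1.4e-05 for cholesterol biosynthesis, 0.0001 for NF-kB targets, 0.0107 for YAP and TEAD targets, 0.00744 for ribosomal proteins and 0.0429 for both other lists. With an estimated correlation none passed (adjusted p = 0.559 for cholesterol, NF-kB, YAP, MAPK and small RNA lists and 0.82 for ribosomal proteins). The remaining 23 lists had an adjusted p from 0.0732 to 0.874. Adjusted over the list alone, 0 members passed in edgeR. Without siRIPK2_3 the ribosomal list had an adjusted p = 0.571 and the YAP list 0.0564. Without siRIPK2_1 or siRIPK2_4 the small RNA list (0.169 and 0.0959) and the MAPK list (0.0961 and 0.0959) missed the threshold, as did the ribosomal list without siRIPK2_4 (0.0959). With the length and GC correction, added after seeing the data, MAPK (0.0585) and small RNA (0.0597) missed it too. The G2/M and mitosis list did not pass with all libraries, passed as lower without siRIPK2_1 (adjusted p = 0.0325) or siRIPK2_4 (0.00532) and as higher without siRIPK2_2 (0.0357). With an estimated correlation its adjusted p was 0.891, 0.997 and 0.882. DNA replication passed as lower without siRIPK2_1 (adjusted p = 4.92e-05, and 0.867 with an estimated correlation) or siRIPK2_3 (0.0497 and 0.934). Without siRIPK2_1, histones passed as higher (adjusted p = 0.000525) and hypoxia and glycolysis as lower (0.0325), with an adjusted p of 0.847 and 0.884 at an estimated correlation. Without siRIPK2_2, the integrated stress response (adjusted p = 0.00649) and autophagy and lysosome (0.0357) passed as lower, with an adjusted p of 0.743 and 0.707 at an estimated correlation. The median and the mean or test differed in sign for the G2/M, apoptosis, TGF-beta, oxidative phosphorylation and other RIP kinase lists, none of which passed. Among single genes, edgeR called 0 of 14306, and 155 had an unadjusted p under 0.05 (95 higher and 60 lower) where chance gives about 715. The balance did not hold in every setting, with 64 higher and 82 lower in limma-voom, 89 and 86 without siRIPK2_1, and 116 lower of 234 without siRIPK2_2, against 154 and 54 in DESeq2. DESeq2 called 9 genes, RIPK2 (adjusted p = 0.0034) and GNA12 among them. GNA12, which encodes a G protein alpha subunit, was at 272 CPM in WT, 48.3 CPM in siNC and 59.5 ± 12.2 CPM in siRIPK2. Limma-voom called 1, Z83844.1, named after its values were seen, which had 20.5 CPM in WT, 0 counts in the other 5 libraries and exons that overlap 2 other listed genes.

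Set against both controls together, the knockdown libraries had lower cholesterol biosynthesis transcripts, and glycolysis transcripts below the mean of 2 controls that themselves differed. Cholesterol biosynthesis fell by a median of 0.34 on the log2 scale, with 21 of 24 members lower, and its median was below both controls in 4 of 4 siRIPK2 libraries. Hypoxia and glycolysis fell by a median of 0.40 with 26 of 30 members lower, although its median was below WT in only 3 of 4 libraries. Against WT alone this list had a median of -0.11 and did not pass (adjusted p = 0.342), and siNC lay above WT by a median of 0.54. NF-kB targets, which lay between the controls, had a median of -0.27 (adjusted p = 0.298). The autophagy and lysosome list had a median below both controls in 4 of 4 libraries but did not pass with all of them (median -0.09, adjusted p = 0.212). RIPK2 and GOLM2 had the lowest unadjusted p of the named genes, with log2 fold changes of -2.93 and -1.38 (unadjusted p of 8.17e-05 and 0.000106).

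The adjusted p in camera was 2.06e-06 for cholesterol biosynthesis and 6.42e-08 for hypoxia and glycolysis. With an estimated correlation it was 0.894 and 0.931, so neither list passed. The remaining 27 lists had an adjusted p from 0.0955 to 0.984, and the median and the mean or test differed in sign for the NOD-RIPK2, interferon, p53, apoptosis, astrocyte, macrophage and small RNA lists. Adjusted over the list alone, 1 member passed in edgeR, LAPTM5, as against siNC. Without siRIPK2_1 or without siRIPK2_2 the count of lists that passed went from 2 to 6, and both lists named here were among the 6 each time. G2/M and mitosis passed as higher without siRIPK2_2 (adjusted p = 0.00136, and 0.866 with an estimated correlation), and DNA replication as lower without siRIPK2_1 (1.1e-05 and 0.906). Also without siRIPK2_1, histones (adjusted p = 0.000505) and ribosomal proteins (0.0297) passed as higher and mitochondrial transcripts (0.0133) as lower, each with an adjusted p of 0.906 at an estimated correlation. Also without siRIPK2_2, the integrated stress response (adjusted p = 0.00297), autophagy and lysosome (0.0458) and mesenchymal markers (0.0262) passed as lower, each with an adjusted p of 0.619 at an estimated correlation. EdgeR called 0 of 13901 genes at the adjusted threshold, with 355 at an unadjusted p under 0.05 (184 higher and 171 lower) against about 695 by chance. The balance turned with the upper quartile (171 higher and 184 lower), the stricter filter (145 and 148), limma-voom (182 and 187) and without siRIPK2_1 (151 and 216) or siRIPK2_2 (266 and 295). DESeq2 called 11, RIPK2 first (adjusted p = 1.74e-06) and GOLM2 among them, and limma-voom called 0. Without siRIPK2_2, edgeR called RIPK2 (adjusted p = 0.0431) and AKAP2, and 561 genes had an unadjusted p under 0.05. Without siRIPK2_1 it called INO80B-WBP1 and AC023055.1, which like AKAP2 are named after their values were seen. AKAP2 and the readthrough gene INO80B-WBP1 overlap other listed genes.

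**Figure D2:**
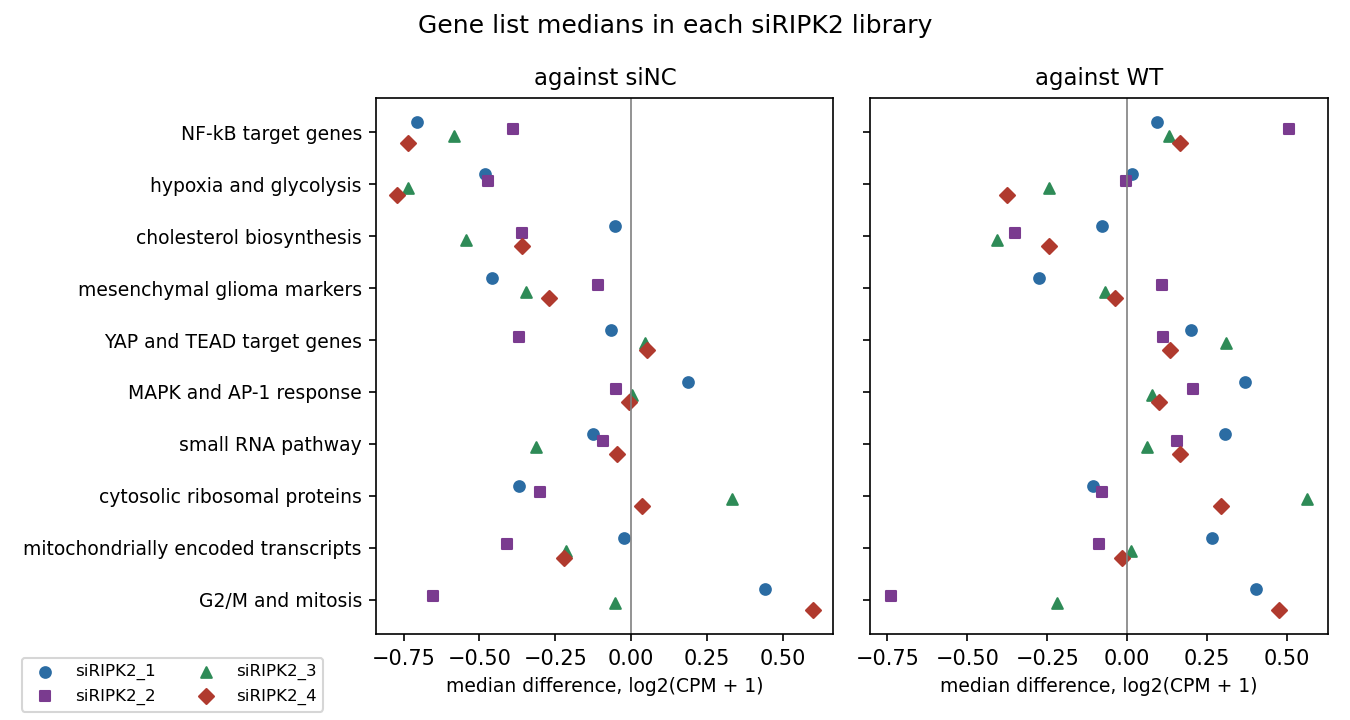
Median difference of each gene list's members in log2(CPM + 1) (x axis) for the 4 siRIPK2 libraries (symbols), against siNC on the left and against WT on the right, for 10 lists (y axis). NF-kB targets lie below siNC by 0.39 to 0.74 and above WT by 0.09 to 0.51, and cholesterol biosynthesis lies below both controls in every siRIPK2 library.

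The control siRNA library itself stood apart from untransfected cells in inflammatory and glycolytic transcripts. NF-kB targets were higher in siNC than in WT by a median log2 of 1.27, with 25 of 29 members higher, and hypoxia and glycolysis by 0.54 with 27 of 30 higher. The small RNA pathway was higher by 0.40 (13 of 15), ribosomal proteins by 0.23 (36 of 37) and mitochondrially encoded transcripts by 0.22 (13 of 13). CSF2 was at 19.7 CPM in siNC and 0.999 CPM in WT, IER2 at 49.1 and 5.36 CPM, and BIRC3 at 45.3 and 13.04 CPM. GNA12 was at 48.3 CPM in siNC and 272 CPM in WT, POSTN at 14.6 and 76.8 CPM, and GANAB, a glucosidase subunit gene, at 279 and 872 CPM. The siNC library also had the strongest GC trend of the 6, with a Spearman rho of 0.236 between GC content and its deviation from the median library across 9461 genes, against -0.135 in WT and -0.103 to 0.0192 in siRIPK2. Its rho with gene length was -0.185, against 0.0633 in WT and -0.106 to 0.184 in siRIPK2, and genes are not independent replicates.

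This compares 1 library with 1 other, with the spread borrowed from the siRIPK2 libraries, and has no replicate check of its own. On that basis the adjusted p in camera was 1.01e-17 for NF-kB targets, 6.79e-10 for hypoxia and glycolysis, 0.00231 for the small RNA pathway, 0.00231 for ribosomal proteins and 0.00363 for mitochondrial transcripts. With an estimated correlation none passed (adjusted p = 0.451 for NF-kB targets and the small RNA pathway, 0.622 for glycolysis, 0.866 for ribosomal proteins and 0.667 for mitochondrial transcripts). The NF-kB median lay above all 10000 random lists of matched expression (percentile 100), as did that of hypoxia and glycolysis. The integrated stress response lay at percentile 0 (median -0.21) without passing in camera, so an extreme percentile alone does not mark a list as changed. The other 24 lists had an adjusted p from 0.0599 to 0.997, and the median and the mean or test differed in sign for the apoptosis, cholesterol, astrocyte, neuron and endothelial lists. Without siRIPK2_1 in the fit, oxidative phosphorylation passed as higher (adjusted p = 0.0415, and 0.627 with an estimated correlation), and without siRIPK2_2 the MAPK list did (0.0387 and 0.688). Adjusted over the list alone, CSF2, IER2 and POSTN passed in edgeR. EdgeR called 0 genes, with 391 at an unadjusted p under 0.05 (92 higher and 299 lower in siNC) against about 715 by chance, and 100 higher and 227 lower with the length and GC offsets. All 5 lists still passed in camera with the length and GC correction, with a median of 1.25 for NF-kB targets and 0.52 for hypoxia and glycolysis. DESeq2 called 11, CSF2, IER2, GNA12, POSTN and GANAB among them, and limma-voom called 0.

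Few genes set all 4 knockdown libraries apart from both controls. In all, 1497 of 14306 genes (10.5%) had all 4 siRIPK2 libraries on the same side of both controls, 710 higher and 787 lower, where chance gives 13.3%. The other 14 ways to split the libraries into 2 and 4 gave between 1160 and 2479 such genes. The split with the most genes set siRIPK2_1 and siRIPK2_3 apart from the rest, and it also had 974 genes at an unadjusted p under 0.05 in edgeR against 355 for the real split. The libraries therefore hold differences that do not follow the groups. With 15 splits the smallest possible share is 0.067, too large for a test at the 0.05 level.

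Each transfected library had its own set of strongly lowered transcripts. Of 9464 genes with a mean of at least 10 CPM, 115 were at least 2-fold below all other 5 libraries in siRIPK2_1, 44 in siRIPK2_2, 77 in siRIPK2_3, 87 in siRIPK2_4 and 57 in siNC, against 3 in WT (FAM110A, GMEB2 and TFE3). At least 2-fold above the other 5 were 22, 8, 11, 9 and 5 genes in the same transfected libraries, fewer than below in each, and 3 in WT. The 5 in siNC were IER2, CD82, GFPT2, CXCL3 and BAHCC1, and the 3 in WT were GNA12, BLOC1S6 and MAP2K4. In siRIPK2_1, ANXA2, which encodes annexin A2, was at 361 CPM where the other libraries had 1964 to 3585 CPM, and PTX3, which encodes pentraxin 3, at 69.5 against 393 to 777 CPM. In siRIPK2_3, the actin bundling gene FSCN1 was at 75.1 against 665 to 827 CPM, IMP3 at 3.06 against 79.4 to 138 CPM, and the interferon receptor gene IFNAR1 at 6.33 against 41.9 to 58.2 CPM. In siRIPK2_4, GCLM, a subunit of the enzyme that limits glutathione synthesis, was at 6.05 against 64.8 to 86.2 CPM and the lysosomal protease gene TPP1 at 26.4 against 176 to 239 CPM. In siRIPK2_2, the kinetochore gene NUF2 was at 11.6 against 38.4 to 63.0 CPM. In siNC, the nuclear pore gene TPR was at 52.2 against 163 to 222 CPM. These genes were chosen after their values were seen, each value is from 1 library with no replicate, and IMP3, PTX3, TPR and BLOC1S6 overlap another listed gene.

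**Figure D3:**
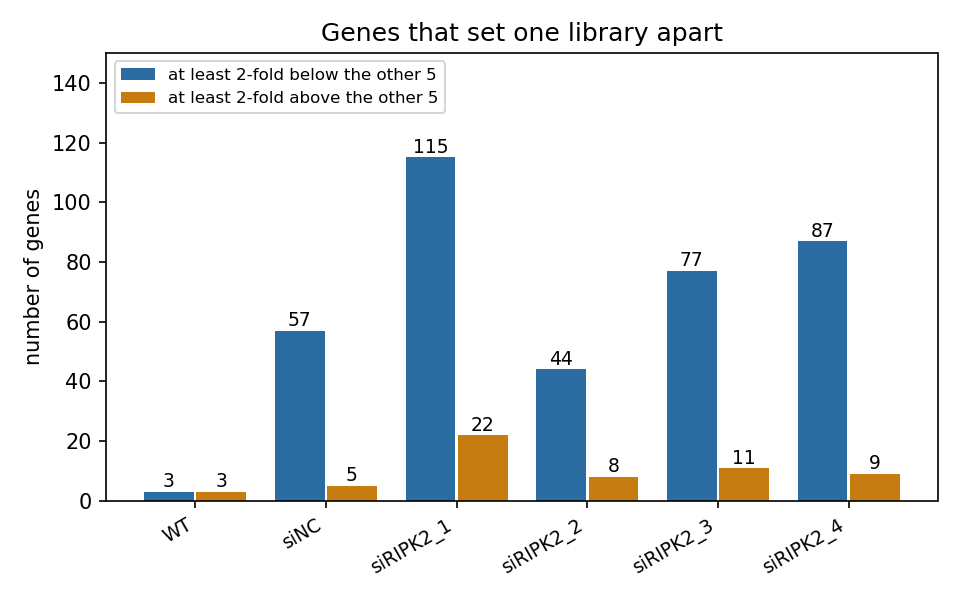
Number of genes (y axis, of 9464 with a mean of at least 10 CPM) that lie at least 2-fold below (blue) or above (orange) all other 5 libraries, for each library. The 5 transfected libraries have 44 to 115 such lowered genes each, and WT has 3.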

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

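All items here are libraries that lay far from the other 3 siRIPK2 libraries, by Dixon's ratio of the gap to the range, above its 95% critical value for 4 samples. Of 166 measures tested (133 genes, 29 lists and 4 library totals or shares), 8 passed, and chance alone gives about 8.3, or 1 in 20.

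The NF-kB target list was higher in siRIPK2_2, at a mean log2(CPM + 1) of 3.96 against 3.57 to 3.60 in the other siRIPK2 libraries (ratio 0.94). The interferon-stimulated list was also higher there, at 4.19 against 3.81 to 3.85 (ratio 0.893). PECAM1, an endothelial marker, was at 2.75 CPM in siRIPK2_2 against 0.664 to 0.984 CPM (ratio 0.847). In siRIPK2_1, the mitotic gene CENPF was at 333 CPM against 114 to 139 CPM (ratio 0.884) and the protease gene PLAU at 438 against 191 to 210 CPM (ratio 0.921). The share of counts from mitochondrially encoded transcripts was 4.71% in siRIPK2_1 against 4.1% to 4.13% (ratio 0.951). In siRIPK2_3, RBMS3 was at 20.2 CPM against 40.1 to 43.7 CPM (ratio 0.849) and BECN1, an autophagy gene, at 63.1 against 44.7 to 47.2 CPM (ratio 0.866). PLAU, RBMS3 and BECN1 overlap other listed genes.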

How the results depend on the processing

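The settings with length and GC offsets and with genes lacking the heptamers were chosen after seeing the data, and all others were planned. The fall of RIPK2 kept its direction and an unadjusted p under 0.05 in every setting that could test it, with log2 fold changes from -3.17 to -2.55 against siNC, -3.56 to -2.93 against WT and -3.38 to -2.73 against both controls. With 0 genes called in edgeR, the DESeq2 Wald test called 74 against siNC, 9 against WT, 11 against both controls and 11 for siNC against WT. Against WT, leaving out the filter called 1 gene and limma-voom called 1, Z83844.1 in both cases. Leaving out single libraries gave 0 to 2 calls against both controls and 0 in the other comparisons. The other normalisations, the stricter filter, robust dispersions, length and GC offsets and the 6089 genes without heptamers gave 0 calls throughout, and the cause of the DESeq2 difference was not tested. Gene lists passed in camera 5, 6, 2 and 5 times (siRIPK2 against siNC, WT and both controls, and siNC against WT), but 0 times with an estimated correlation and 0 times in fry in each comparison. The simulated shifted list was also missed with an estimated correlation, but its genes were independent, so this does not favour the preset correlation for correlated lists. Without single siRIPK2 libraries, 5 to 7, 4 to 9, 2 to 6 and 5 to 6 lists passed. Of the 18 list calls, 13 held under DESeq2 size factors, each left-out library and the length and GC correction, and 0 changed direction. The genes on the same side of both controls numbered 1486 with DESeq2 size factors and 1227 of 11858 with the stricter filter. None of the 23 named genes besides RIPK2 changed direction in 312 refits, and DESeq2 alone called 14 of them. The naming rule had asked for all 4 siRIPK2 libraries on the same side of both controls, so a change of direction was unlikely from the start. Of 109 list members, 2 near 0 (KRT8 and KRT14) changed sign in some setting. No paired analysis was possible because the control groups have 1 library each and share fewer than 2 replicate numbers with siRIPK2. Depth was similar across libraries. Both the spread between siRIPK2 libraries and the lone controls bear on which fold changes can be called, and their parts were not separated. Simulated 4-fold changes were recovered in 38% of cases against siNC, 62% against both controls and 10% for siNC against WT.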

Other observations

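Of the tests reported here, those on heptamers of the siRIPK2 and siNC libraries were chosen only after the result was seen. Those on the level of the siNC library and on how many siRIPK2 libraries had an NF-kB median below WT were chosen after it too. So were the tests of base composition for microRNA sites and of those sites in the transfected libraries. The tests of other microRNA sites and of length and GC trends were chosen before their own results were seen. The former was chosen after let-7 and miR-29 sites had been seen to be low in WT. The length and GC correction used in the latter was added after the data had been seen.

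The 4 siRIPK2 libraries differed in cell cycle transcripts. The G2/M and mitosis list had a median log2 difference from siNC of 0.44 in siRIPK2_1, -0.65 in siRIPK2_2, -0.05 in siRIPK2_3 and 0.60 in siRIPK2_4. Against WT the values were 0.40, -0.74, -0.22 and 0.48. DNA replication and S phase genes were lower in siRIPK2_2 as well, by a median of -0.50 against siNC and -0.57 against WT, and were at 0.30 and 0.23 in siRIPK2_1. BIRC5, an inhibitor of apoptosis expressed in mitosis, was at 177 CPM in siRIPK2_4 where the other 5 libraries had 18.2 to 72.1 CPM. Keratin 75 (KRT75) stood at 467 CPM in siRIPK2_1 against 50.2 to 122 CPM elsewhere, and KRT16 at 55.8 CPM in siRIPK2_2 against 2.95 to 16.02 CPM. FGF5, a growth factor gene that overlaps another listed gene, was at 186 CPM in siRIPK2_4 against 19.1 to 55.7 CPM. These are values of single libraries with no test.

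Transcripts low in a single siRIPK2 library often shared a heptamer in the 3' UTR: on even-numbered chromosomes 48.9% of 131 carried the heptamer picked for their library on odd-numbered ones, against 15.1% of other transcripts (1-sided Fisher's exact test, 1.64e-19). The counts of the 4 libraries were pooled, so a gene could enter once per library. Unlike the z values, these shares were not adjusted for UTR length. The picked heptamers were GCCAAAG in siRIPK2_1, GAAGTAT in siRIPK2_2, CTGGAAA in siRIPK2_3 and TGATCAC in siRIPK2_4. The same Fisher's test did not pass for siRIPK2_2 alone (18.8% against 13.3%, 0.363), nor for TCGGAGA in siNC (9.09% against 2.16%, 0.0828). Over all chromosomes the shares were 36.4% against 12.3% in siRIPK2_2 and 14.04% against 2.21% in siNC. These shares include the chromosomes used to pick the heptamers, so they are not a test. Base composition of the 3' UTR is argued against, since a share of at most 0.0095 of heptamers with the same composition was as low. The use of 1 siRNA or pool in all 4 libraries is argued against by heptamers picked from each library's difference to both controls, which were the same 4. On even-numbered chromosomes 0 of 12 tests in another siRIPK2 library had a z under -3 (-1.74 to 1.17, own library -13.4 to -5.44). A heptamer planted in all 4 at a log2 of -0.3 gave 12 of 12, and weaker shared effects were not simulated. All 4 heptamers occur in the RIPK2 mRNA, as do 13.98% of all heptamers (1-sided exact binomial test, 0.000382). That test takes all heptamers as equally likely, which was not checked for the picked ones. The siNC heptamer occurs in the RIPK2 mRNA too, with a z on even-numbered chromosomes of -4.38 against -4.41 in siRIPK2_2, so this match does not set the siRIPK2 libraries apart. A candidate explanation is that each library received a different siRNA that also lowered transcripts matching its seed, a hypothesis only, since the siRNA sequences were not used here and genes are not independent replicates.

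In WT, transcripts with let-7 sites (z -5.22) and miR-29 sites (z -7.23) were low relative to the transfected libraries. The shift was small, with a log2 effect of -0.061 for the miR-29 site, which had the lowest z of all heptamers in WT. The heptamer picked for WT on odd-numbered chromosomes was a different one, and its z on even-numbered ones was only -0.21. The split search therefore gave no heptamer that held in WT. Sites of 15 other broadly expressed microRNAs had a mean z of -1.81 ± 1.38 (SD) in WT against 0.27 ± 0.58 for 8 tissue-restricted ones (exact permutation test over 490314 splits, 2-sided p = 0.000428, adjusted over the 6 libraries 0.00257). The same 15 sites averaged 1.16 in siNC against -0.42 for the restricted ones (p = 0.0234 in the same permutation test, adjusted 0.0702), and 0.80, 0.23, 0.12 and -0.09 in siRIPK2_1 to siRIPK2_4 (adjusted p from 0.271 to 0.937). Each library was scored against the median of its other 5, and for a transfected library most of these were transfected too. Release shared by the transfected libraries would largely cancel there, so means near 0 in them do not speak against it. Base composition is argued against, since 0 of 10000 random sets of heptamers with the composition of those 15 sites had as low a mean z (lowest -1.09). This is consistent with a hypothesis that transfected siRNA competed with microRNAs and released their targets, but it rests on 1 untransfected library, whose other differences stay open, and release in each transfected library was not shown.

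NF-kB targets were lower in siRIPK2 than in siNC, and RIPK2 acts upstream of NF-kB. Gene length and GC trends of the libraries are argued against as the whole cause, since the median was -0.66 after correction (95% bootstrap interval over members -1.11 to -0.35) and -0.72 before. The median was below WT in 0 of 4 siRIPK2 libraries (0.09 to 0.51 above), but with 1 WT library and an adjusted p = 0.559 with an estimated correlation a fall below untransfected cells is not excluded, and a fall from a level raised by transfection also stays open. The lone siNC library lay 0.391 above the next highest library in mean log2(CPM + 1), and whether that library, its siRNA or RIPK2 loss set the difference cannot be told apart with 1 siNC library.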
